A study of Oryza sativa with 14 samples.

How the data were processed

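RNA from roots and shoots of etiolated rice seedlings was measured on 14 one-colour Affymetrix rice arrays, 1 array for each of 14 combinations of genotype, tissue and gas. The genotypes were wild type (WT) and the ethylene-response mutants mhz1, mhz4 and mhz5, with mhz1 measured in roots only. The titles of both WT root arrays carry the mark mb, which no other title has. Its meaning is not given in the titles, and every root comparison of a mutant with WT is aligned with it. Per the labels' protocols, seeds germinated in the dark at 37 °C for 2 days. Seedlings aged 3 days were kept for 8 h at 28 °C in the dark with 10 ppm ethylene, and seedlings in air served as controls. For the ethylene arrays the labels also give water of 1.5 to 1.7 cm. No duration, temperature or water depth is given for the air arrays, so any difference in these would be part of every ethylene effect here. Biotin-labelled cRNA was made from 6 µg of total RNA, per the labels' protocols.

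The deposited values are 1 intensity per probe set and array on a linear scale, and MAS5 is the tool named in the submitters' processing notes. Its version, background settings and scaling target are not given in the sources used here. The authors' values were positive on every array, with lowest values from 2.15 to 2.47 and medians from 16.3 to 17.1. The sorted values of the arrays were close to one another, with a median coefficient of variation of 2.43% over ranks, although pairs of arrays shared only 3 to 265 identical values (median 53 over 91 pairs). The deposited arrays therefore had nearly the same distribution, and whether a step before deposit brought this about is not stated. Detection calls were not used here.

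The table held 57381 probe sets, of which 123 Affymetrix control probe sets were left out and 57258 were used. Each array was multiplied by 1 factor (3.87 to 4.10) to bring its mean, without the lowest and highest 2% of values, to 500. Signals below are on that scale. Differences are on the log2(signal + 32) scale, which understates the change of dim probe sets. Probe sets were named through the platform annotation of the array and the current gene table of rice. In that annotation 22436 probe sets had 1 gene, 95 had several and 34727 were unnamed here. The 1-gene probe sets covered 17905 genes, all 17905 of which were found in the gene table, and 2457 of these had an informative name. A gene was represented by its probe set with the highest mean signal, and no gene was named from a probe set with several. Probe sets of close paralogs may share transcripts.

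With 1 array per group, a difference between 2 arrays has no replicate check and no p-value. For each of these pairs, probe sets with a signal of at least 200 in the brighter array were compared, those at least 2-fold apart were counted, and the median of each gene list was ranked as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. Such a percentile describes those arrays only, and the random lists ignore the correlation between members of a list.

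Tests came from 1 limma fit over the 14 arrays, with 7 genotype-by-tissue terms and 2 ethylene terms (1 per tissue), for the 23186 probe sets with a signal of at least 200 on at least 2 arrays. The fit had 5 residual degrees of freedom, 3.35 prior degrees of freedom and a median residual SD of 0.12 on the log2 scale. Variances were moderated with a trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In this fit the genotypes stand in as replicates of the ethylene effect, and the air and ethylene arrays of a genotype stand in as replicates of that genotype. The residual spread is therefore the difference in response between genotypes plus array noise, not the spread between replicate seedlings, and any difference in growth or hybridisation is part of a genotype's effect. All adjusted p-values of genes are limma's. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Differences of an effect between root and shoot were tested as contrasts of the same fit. These 3 contrasts were added after seeing the data.

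Before the data were examined, 22 gene lists were fixed in words, together with the rule for named genes. The lists cover the mutated loci, ethylene biosynthesis, ethylene perception and signalling, ERF transcription factors, the carotenoid pathway, abscisic acid (ABA) biosynthesis and catabolism, LEA and dehydrin proteins, auxin, cytokinin, gibberellin, jasmonate, expansins, pathogenesis-related proteins, class III peroxidases, low-oxygen and fermentation genes, photosynthesis genes, root markers, seed and endosperm markers, histones and cell cycle, ribosomal proteins, heat shock proteins, and aquaporins. They were translated into gene symbols once the annotation had been seen and before any gene's value was read, and the patterns for heat shock proteins and phosphate transporters were corrected for false matches. Another 3 lists (diterpenoid phytoalexin biosynthesis, iron acquisition, phosphate transporters) were added after the data were seen. The root marker list shares its nicotianamine synthase genes with the iron acquisition list. The rule names the 12 largest changes in each direction of an ethylene comparison, the 6 largest of a mutant comparison, the mutated loci, and from each list up to 4 members with the largest change plus the members past the threshold. Among the mutated loci only MHZ4 has a probe set named in the annotation, and MHZ1 and MHZ5 were not analysed here.

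Alternatives were quantile normalization, pseudocounts of 16 and 64, signal filters of 100 and 400 or none, a fold threshold of 1.5, variances without a trend, fits on the arrays of 1 tissue, and leaving out each genotype in turn. After seeing the data, fits without the WT air array of a tissue, the ethylene arrays in place of the air arrays, and all alternatives for the 3 contrasts between tissues were added. A value without a test counted as moved when it changed by more than 0.1 on the log2 scale, and a count when it changed by more than 1.5 times. The limma procedure was tested on simulated data with 200 changed probe sets among 23186 for each of the 7 comparisons. In the mean ethylene effect in roots it recovered 90% of 2-fold and 99% of 4-fold changes with 4.1% false calls, and in the mhz5 root comparison 80% of 2-fold changes. False calls exceeded 5% for ethylene in shoots (7.8%), mhz4 roots (6.6%) and mhz5 roots (5.3%). The simulated noise was independent and alike on all arrays, with no array standing apart. These rates therefore check the procedure and do not give the error of the real calls. The number of arrays limits the precision of every value. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.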

Results

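Transcript levels were measured in roots and shoots of dark-grown rice seedlings of WT, mhz1, mhz4 and mhz5, in air and after 8 h in 10 ppm ethylene. The series was set up to characterise these mutants, which were isolated for altered ethylene responses. From published work on the mutants, MHZ1 encodes a histidine kinase, MHZ4 a chloroplast protein of ABA synthesis and MHZ5 a carotenoid isomerase that acts upstream of ABA synthesis. There were 8 root arrays (4 genotypes) and 6 shoot arrays (3 genotypes), with 1 array in each group. Between 19295 and 19821 probe sets reached a signal of 200 on an array. Spearman correlations between arrays over probe sets were 0.976 to 0.991 within a tissue and 0.914 to 0.929 between tissues.

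MHZ4 had its lowest signals in the mhz4 arrays. In roots it read 189 and 186 (air and ethylene) in mhz4, against 450 and 398 in WT, 338 and 253 in mhz1, and 350 and 373 in mhz5. In shoots it read 193 and 239 in mhz4, 657 and 550 in WT, and 469 and 505 in mhz5. The mean difference between mhz4 and WT was -1.05 in root (adjusted p = 0.0045) and -1.36 in shoot (adjusted p = 0.00103). The labels do not give the nature of the mutation, so transcript level checks the labels only in part.

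**Figure D1:**
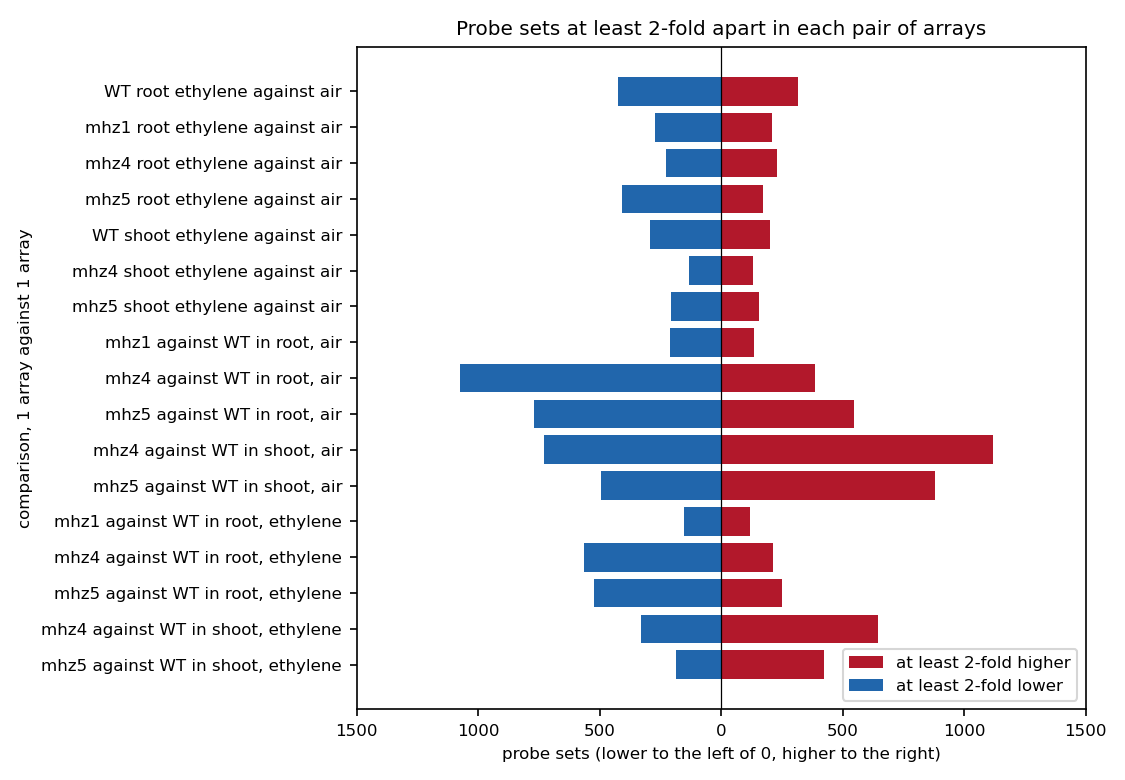
Number of probe sets at least 2-fold higher (red, right of 0) or lower (blue, left of 0) in each comparison of 1 array with 1 array, among probe sets with a signal of at least 200 in the brighter array. The mhz4 and mhz5 arrays differed from WT at 1317 to 1844 probe sets in air, and the mhz1 root array at 346.

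The first comparison asked how WT roots responded to ethylene. Dehydrins and other late embryogenesis abundant (LEA) proteins, which accumulate in dry or ABA-treated tissue, stood lower after ethylene. RAB21 read 11971 in air and 89.1 in ethylene (log2 difference -6.63), LEA19 read 5875 and 238 (-4.45), and the median of the 8 measured members was -4.58, below all 10000 random lists (percentile 0.0). The arginine decarboxylase ADC2 read 3340 and 357 (-3.12), the sugar transporter SWEET12 3009 and 332 (-3.06), and the phosphatase PP2C30 1114 and 144 (-2.70). Genes of iron acquisition stood higher, among them the iron-phytosiderophore transporter YSL15 (1498 and 5203, 1.77) and the iron transporter IRT2 (166 and 606, 1.69), and the 12 members had a median of 1.13 (percentile 100). That list was added after the data were seen, so its percentile is no independent support. The lipoxygenase LOX3 (98.3 and 686, 2.46), the expansin EXPA6 (157 and 857, 2.24), the copper transporter COPT1 (1168 and 3818, 1.68) and the organ-size regulator ARGOS (613 and 2000, 1.66) were also higher. In all, 743 of 20381 compared probe sets were at least 2-fold apart, 317 higher and 426 lower. The medians of ABA biosynthesis and catabolism (-0.86, percentile 0.01), the carotenoid pathway (-0.52, 0.86), expansins (-0.11, 0.54) and ERF transcription factors (-0.70, 2.01) lay low among random lists. Those of root markers (0.60, 100), low-oxygen genes (0.46, 99.98) and auxin genes (0.18, 100) lay high. Expansins had a mean of -0.0006, with 1 member at least 2-fold higher and 0 lower, so that list as a whole was not lowered.

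Setting the mutants beside WT addressed which ethylene responses the mutations alter. In mhz1 roots the same dehydrins were lower, with -3.94 for RAB21 and -2.91 for LEA19 and a list median of -2.59. In mhz4 and mhz5 roots they were low in air already, so that RAB21 differed by -0.49 and -0.27 between the gases. SWEET12 differed by -2.42 in mhz1 roots but by -0.03 in mhz4 and 0.04 in mhz5. ADC2 and ARGOS responded in all 4 genotypes, with -3.12 to -3.44 for ADC2 and 1.29 to 1.66 for ARGOS. At least 2-fold differences numbered 483 in mhz1 roots, 456 in mhz4 and 577 in mhz5. Shoot-marker photosynthesis genes had a list median of 1.25 in mhz4 roots (4 measured, percentile 99.99), where RBCS read 193 in air and 1528 in ethylene, against 116 to 171 on the arrays of the other genotypes, and the cause was not tested. On probe sets chosen in the other genotypes, the median response in their direction was 1.18 in WT (323 probe sets), 1.21 in mhz1 (356), 0.80 in mhz4 (455) and 0.77 in mhz5 (441). Across 23186 probe sets, which are not independent replicates, the root response of WT correlated with that of mhz1 at r = 0.738, of mhz4 at 0.375 and of mhz5 at 0.282. None of these differences between responses was tested, since each response rests on 1 pair of arrays.

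**Figure D2:**
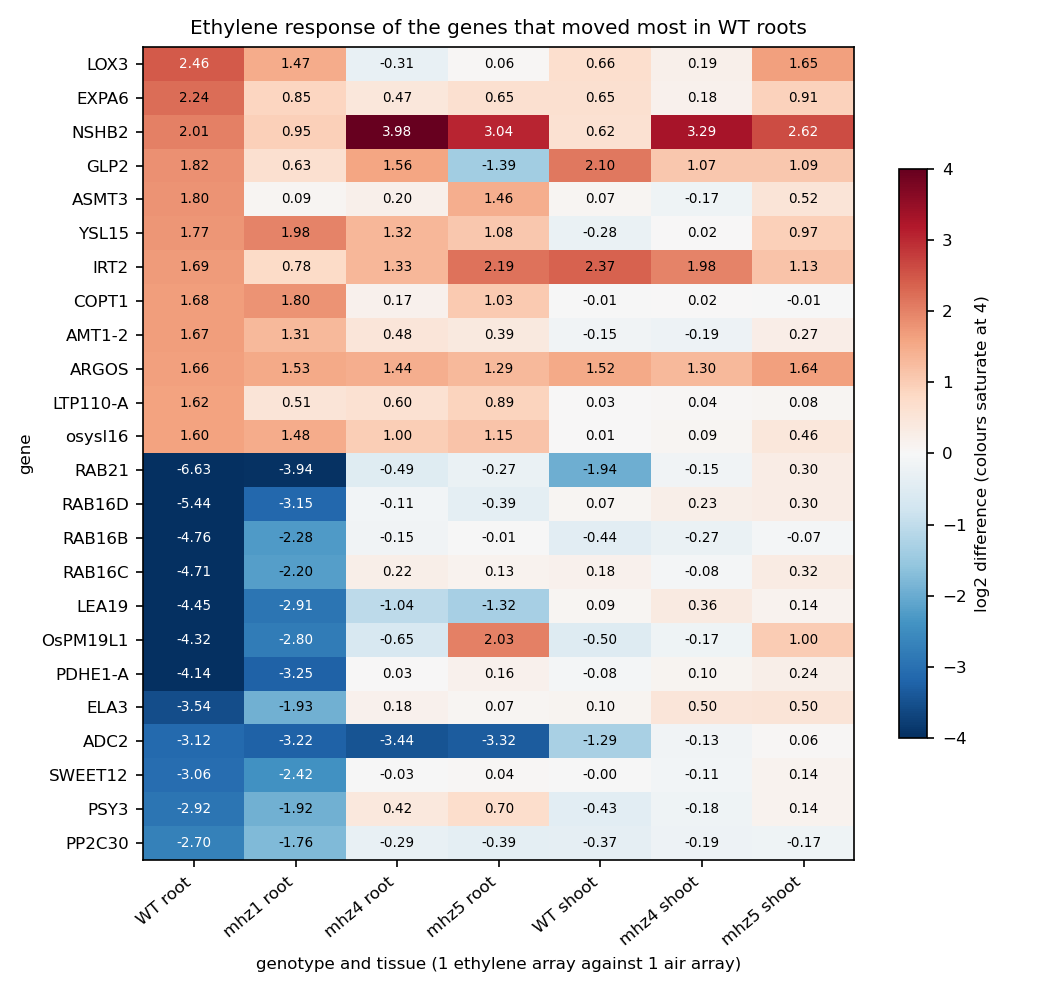
Ethylene response (log2 difference, 1 ethylene array against 1 air array) of the 24 genes named for WT roots, in each genotype and tissue. RAB21 and the RAB16 genes are lower with ethylene in WT and mhz1 roots (-2.20 to -6.63) and near 0 in mhz4 and mhz5 roots (-0.49 to 0.22), while ADC2 is lower in all 4 root comparisons.

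Averaged over the 4 genotypes, ethylene raised the receptor gene ETR2 and iron acquisition transcripts in roots. ETR2 rose by 1.19 (SE 0.06, adjusted p = 6.57e-05, higher in all 4 genotypes) and ARGOS by 1.48 (SE 0.08, adjusted p = 8.38e-05). In the ethylene signalling list, 4 of 7 members passed the threshold: ETR2 and the receptor gene ERS1 (0.30) rose, while the transcription factor gene EIL1B (-1.28) and EIN2 (-0.48) fell. Of 12 iron acquisition genes, 7 rose and none fell (8 adjusted over the list alone), among them YSL15 (1.54), IRT2 (1.50) and the nicotianamine synthase gene NAS3 (0.90). The iron list passed camera (adjusted p = 7.19e-08; adjusted p = 0.045 with an estimated correlation). Since the list was added after the data were seen, these p-values are no independent support. Among named genes past the threshold, the largest decreases were those of CRSH2, a homolog of bacterial stringent-response enzymes (-3.43, SE 0.24, adjusted p = 0.000276), ADC2 (-3.27, SE 0.19, adjusted p = 0.000109) and LEA19 (-2.43). The aldehyde oxidase gene AO-1 (-1.22), the homeobox gene Hox22 (-1.26) and OsICS (-1.09) fell as well. NSHB2, a haemoglobin gene, rose by 2.49 (SE 0.52, adjusted p = 0.0318).

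In the other lists fewer members passed in roots. LEA19 was the 1 of 6 LEA and dehydrin genes to pass (4 adjusted over the list alone; camera adjusted p = 0.00118; adjusted p = 0.7 with an estimated correlation). Among 12 low-oxygen and fermentation genes, 4 rose: NSHB2, the dikinase gene PPDK1 (1.34), the alcohol dehydrogenase gene Adh2 (adjusted p = 0.0137) and the pyruvate decarboxylase gene PDC2 (0.40). That list's camera adjusted p was 0.00109, and the adjusted p = 0.456 with an estimated correlation. Of 15 root markers, NAS3, AMT1-2 (0.96) and AMT1-1 (0.30) rose (camera adjusted p = 0.000193; adjusted p = 0.456 with an estimated correlation). In the ABA list only AO-1 of 7 fell, and in the auxin list PIN5 (0.85) and IAA15 (0.36) rose out of 40, and each list had a camera adjusted p of 0.0327 (adjusted p = 0.56 and 0.7 with an estimated correlation). Expansins split between EXPB18 (0.61) and EXPA8 (-0.52), and heat shock genes between HSP23.2 (0.74) and HSP18.6 (-0.64), while the aquaporin gene SIP2-1 fell (-0.46). Adjusted over the list alone, 2 of 23 expansins rose and 4 fell. Gibberellin genes went both ways, with EUI1 (0.93) and GA20OX2 (0.92) up and CPS1 (-1.77) down. Among 26 cytokinin genes LOGL1 (0.83) and CKX11 (0.52) rose and ORR4 (-0.45) fell (4 and 6 adjusted over the list alone), and among 30 pathogenesis-related genes OC-X (0.71) rose and Chib3H-h (-2.22), GER3 (-0.66) and OC-I (-0.21) fell (4 and 4 adjusted over the list alone). No member of the ethylene biosynthesis, ERF, carotenoid, jasmonate, photosynthesis, peroxidase, seed, cell cycle, ribosomal, phytoalexin or phosphate transporter lists passed in roots.

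In total 1139 of 23186 probe sets passed in roots, 539 higher and 600 lower. The count was 647 without the WT root arrays, 499 without the mhz1 root arrays and 650 without the WT root air array alone. Without that array 3 of the iron genes passed (YSL15, IRT2 and NAS3; camera adjusted p = 2.55e-07; adjusted p = 0.0915 with an estimated correlation), NSHB2 (adjusted p = 0.0773), Adh2 (0.0585), AMT1-1 (0.127), AMT1-2 (0.122), GER3 (0.0621), EUI1 (0.0658), LOGL1 (0.0524), OC-I (0.0907), EXPB18 (0.107), EXPA8 (0.162), HSP23.2 (0.172), HSP18.6 (0.13) and SIP2-1 (0.13) did not, and the ABA and auxin lists had camera adjusted p = 0.0977 and 0.191. LEA19 was lost without mhz1 (adjusted p = 0.125), as was NAS3 (0.0566), CPS1 without mhz1 or mhz4 (0.106 at most), ORR4 without mhz1, mhz4 or mhz5 (0.114 at most), and NSHB2 without WT, mhz4 or mhz5 (0.102 at most). The calls of OC-I, EXPB18 and SIP2-1 ended without any 1 of the 4 genotypes (0.0899, 0.126 and 0.187 at most), those of EXPA8 and HSP23.2 without WT, mhz4 or mhz5 (0.166 and 0.181 at most), and those of Adh2, AMT1-2 and LOGL1 without WT or mhz1 (0.0645, 0.186 and 0.068 at most). HSP18.6 was lost without WT, mhz1 or mhz5 (0.132 at most), AMT1-1 without WT, mhz1 or mhz4 (0.129 at most), and EUI1 without WT or mhz5 (0.0669 at most). ARGOS, ETR2, ERS1, EIL1B, EIN2, YSL15, IRT2, CRSH2, ADC2, AO-1, Hox22, OsICS, PPDK1, PDC2, PIN5 and GA20OX2 passed without each genotype in turn and without that array.

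In WT shoots, ethylene went with higher levels of iron acquisition genes and lower levels of the fermentation gene PDC1. The nicotianamine synthase genes NAS1 (470 in air, 5934 in ethylene, 3.57) and NAS2 (400 and 3397, 2.99), IRT2 (2.37) and the aminotransferase gene NAAT1 (447 and 2106, 2.16) were higher, and the 12 iron genes had a median of 0.87 (percentile 100). Here too the percentile is that of a list added after the data were seen. The pyruvate decarboxylase gene PDC1 read 7310 in air and 99.3 in ethylene (-5.81), and PPDK2 read 1882 and 94.4 (-3.92). Both rest on the WT shoot air array, since PDC1 read 56.1 to 364 and PPDK2 164 to 310 on the mhz4 and mhz5 shoot arrays. At least 2-fold differences numbered 495 in WT shoots, 264 in mhz4 and 363 in mhz5. The WT shoot response on probe sets chosen in the mutants had a median of 0.68 (229 probe sets), against 0.74 in mhz4 (276) and 0.94 in mhz5 (250). The photosynthesis list had medians of 0.21 in WT, -0.38 in mhz4 and -0.48 in mhz5 (percentiles 99.94, 0.0 and 0.0), and responses of mhz4 and mhz5 correlated at r = 0.537 across probe sets, against 0.282 and 0.248 with WT.

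Averaged over the 3 genotypes measured in shoots, ethylene raised ARGOS by 1.49 (SE 0.09, adjusted p = 0.000598) and ETR2 by 0.83 (SE 0.07, adjusted p = 0.00147), each higher in 3 of 3 genotypes. The iron transporter gene IRT2 (1.83), OsIDI1 (1.47) and NAAT1 (1.35) rose, as 3 of 12 iron acquisition genes (6 adjusted over the list alone; camera adjusted p = 0.000101; adjusted p = 0.136 with an estimated correlation). These camera values again belong to a list added after the data were seen. BURP16 (1.53), the ammonium transporter gene AMT1-1 (0.60) and the transcription factor gene JAMYB (1.23) rose too. The beta-glucosidase gene BGLU16 (-1.27), ILL3 (-0.96), the zinc transporter gene ZIP4 (-0.88), CRSH2 (-1.54) and EIL1B (-1.09) fell, as did the receptor gene ERS2 (-0.66). In further lists LOGL1 (0.82), the germin-like gene GER4 (0.51), PRX74 (0.44) and PDC2 (0.31) rose, while the cytokinin-activating gene LOG (-0.42), SLR1 (-0.34), AOS4 (-0.92), GER3 (-0.78) and GER1 (-0.57) fell. No member of the ethylene biosynthesis, ERF, carotenoid, ABA, LEA, auxin, expansin, photosynthesis, seed, cell cycle, heat shock, aquaporin, phytoalexin or phosphate transporter lists passed in shoots with all arrays fitted. Ribosomal protein genes had a median of 0.08 with 0 of 21 past the threshold, and camera gave adjusted p = 0.000416 (adjusted p = 0.787 with an estimated correlation).

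In all, 512 probe sets passed in shoots, 186 higher and 326 lower. The count was 786 without WT, 157 without mhz4, 139 without mhz5, 781 without the WT shoot air array and 210 when only shoot arrays were fitted. ARGOS, ETR2, BGLU16, ILL3, ZIP4, GER4 and AMT1-1 passed without each genotype in turn. Without the WT shoot air array IRT2 (adjusted p = 0.0529), NAAT1 (0.0822), EIL1B (0.0866) and CRSH2 (0.0876) were lost, and 1 iron gene passed (camera adjusted p = 0.00089; adjusted p = 0.539 with an estimated correlation). In that fit 4 of 13 photosynthesis genes were lower with ethylene (camera adjusted p = 0.000328; adjusted p = 0.539 with an estimated correlation) and 2 of 40 auxin genes higher, and expansins (1 higher, 1 lower) and aquaporins (1 higher, 2 lower) also had members past the threshold. LOG (0.0636), SLR1 (0.0931) and AOS4 (0.0569) were lost without it too. Leaving out mhz4 also ended the calls of IRT2 (0.112), NAAT1 (0.18), CRSH2 (0.159), LOG (0.137), SLR1 (0.237) and AOS4 (0.118), and leaving out mhz5 those of EIL1B (0.137) and GER1 (0.0824). OsIDI1 (0.184 at most), ERS2 (0.0753), LOGL1 (0.214), PRX74 (0.228), PDC2 (0.136) and GER3 (0.113) were lost without mhz4 or mhz5, JAMYB without mhz4 (0.0559) and BURP16 without mhz5 (0.051). Between roots and shoots, 89 probe sets rose in both and 117 fell in both, against 4.32 and 8.44 for independent lists.

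The mhz1 mutant was compared with WT in roots. BC1, a COBRA-like cell wall gene (LOC4333114), was higher in mhz1 (1.27, SE 0.07, adjusted p = 8.73e-05; 1.27 in air and 1.27 in ethylene), as were the kinase gene CIPK17 (1.27), the actin-depolymerising factor gene ADF11 (1.13) and the expansin gene EXPB3 (1.04). A chitinase gene (LOC4351188) was lower (-2.45, SE 0.34, adjusted p = 0.0184), as were the expansin genes EXPB18 (-1.51) and EXPA31 (-1.47), MADS25 (-1.23), SPX2 (-1.04) and the cytokinin response regulator gene RR4 (-0.69). In air, the median of the 8 LEA and dehydrin genes was -2.30 (percentile 0.0), with -2.42 for RAB21, but none of the 6 tested members passed over both gases, and their median over both gases went from -1.10 to 0.71 without the WT root air array. In the expansin list 1 of 23 was higher and 2 lower. The 21 ribosomal protein genes had a median of -0.13 with 0 past the threshold (2 adjusted over the list alone), a camera adjusted p of 1.46e-05 and adjusted p = 0.783 with an estimated correlation, and the jasmonate list, with a median of 0.12 and 0 of 32 past the threshold, had 0.0299 and adjusted p = 0.783 with an estimated correlation.

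Over both gases 289 probe sets differed between mhz1 and WT, 191 higher and 98 lower. The count was 66 without the WT root air array, 67 with mhz4 left out of the fit, 189 with mhz5 left out and 118 when only root arrays were fitted. BC1 (adjusted p = 0.00276), EXPB18 (0.0382) and the chitinase gene (0.0322) passed without the WT root air array, and the other named genes did not (0.0587 to 0.288). With mhz4 left out, the chitinase gene was lost (0.0883), along with EXPB3 (0.061), SPX2 (0.0911) and RR4, which was also lost without mhz5 (0.0898 at most). The jasmonate list had camera adjusted p = 0.266 without the WT root air array. In air alone 346 probe sets were at least 2-fold apart.

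Genes lower than in WT in both mhz4 and mhz5 roots included EXPB18, GER3, TIP1-2 and SWEET12. The expansin gene EXPB18 differed by -2.87 in mhz4 (SE 0.16, adjusted p = 8.25e-05) and -2.76 in mhz5 (adjusted p = 0.000151), the germin-like gene GER3 by -2.28 and -2.31, the aquaporin gene TIP1-2 by -2.10 and -2.06, and SWEET12 by -4.24 and -4.05. The phosphatase genes PP2C30 (-2.28 and -2.32) and PP2C68 (-2.29 and -2.07) were lower as well. Higher in both were LOX3 (3.13 and 2.76), NSHB2 (2.84 and 3.35), the beta-glucosidase gene BGLU3 (2.43 and 2.21) and THT2 (1.78 and 2.09), while YSL15 (1.72) and the tryptophan decarboxylase gene TDC2 (1.55) were among the highest in mhz5. In air, the 8 LEA and dehydrin genes had medians of -4.18 in mhz4 and -4.16 in mhz5 (percentile 0.0 each), the ABA list -1.13 and -1.20 (0.01 each) and the carotenoid list -1.17 and -1.24 (0.34 and 0.13).

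Among the lists, 6 of 12 iron acquisition genes were higher in mhz5 roots, including IRO3 (1.48), IRT2 (1.35) and NAS3 (1.12), and camera gave adjusted p = 3.13e-05 (adjusted p = 0.11 with an estimated correlation). None passed in mhz4 roots, with a median of 0.47. The iron list was added after the data were seen, so its p-values are no independent support. Expansins split, with EXPB3 (1.32 and 1.18) and EXPA2 (0.84 and 0.94) higher and EXPB18, EXPA31 (-1.88 and -1.61) and EXPA10 (-0.74 and -0.67) lower. The receptor gene ERS2 was lower in both (-0.90 and -1.02), the ABA 8'-hydroxylase gene ABA8OX2 was lower (-1.61 and -1.30) and the phytoene synthase gene PSY2 was lower (-0.78 and -0.92). Of 6 tested LEA and dehydrin genes, LIP9 alone passed in mhz4 (-0.86) and none in mhz5, 5 passed adjusted over the list alone in each, and camera gave adjusted p = 0.034 and 0.0242 (adjusted p = 0.64 and 0.781 with an estimated correlation). Root markers had 4 of 15 higher and 1 lower in mhz4 and 5 higher and 1 lower in mhz5, with the nitrate transporter gene NRT2.2 at 1.73 and 1.46 and camera adjusted p = 0.0206 and 0.000416 (adjusted p = 0.64 and 0.582 with an estimated correlation). The cell cycle list in mhz4 (H2B.7 at 0.42 and H2B.10 at 0.35 of 32) and the low-oxygen list in mhz5 had camera adjusted p = 0.0206 and 0.00918, with adjusted p = 0.64 and 0.582 with an estimated correlation. In the auxin list IAA20 (-2.09 and -1.77) and IAA9 (-1.25 and -1.01) were lower. Small heat shock protein genes split between HSP18.8 (1.81 and 1.47) and HSP17.9A and HSP18.0 (-0.57 to -0.74). Among phosphate transporter genes OsPht1;8 was higher in both (0.80 and 0.70), and in the cytokinin list LOGL1 was higher (0.93 and 0.95) and LOGL5 lower (-0.80 and -0.65).

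Over both gases 3443 probe sets differed from WT in mhz4 roots (1551 higher, 1892 lower) and 2219 in mhz5 roots (1008 higher, 1211 lower). Without the WT root air array, which leaves 1 WT root array, the counts were 853 and 644, and with mhz4 left out the mhz5 count was 1253. Without that array BGLU3, EXPB18, GER3, TIP1-2, EXPA31, EXPB3, EXPA2, EXPA10, ERS2, IAA20 and NRT2.2 still passed in both mutants, PP2C68 (0.027), IAA9 (0.0301) and ABA8OX2 (0.0401) in mhz4, and TDC2 (0.0171), HSP18.0 (0.047) and, of the iron genes, IRO3 (0.0456) in mhz5. LOX3 (adjusted p = 0.0942 in mhz4 and 0.189 in mhz5), NSHB2 (0.131 and 0.112), SWEET12 (0.0541 and 0.0789), PP2C30 (0.136 and 0.16), THT2 (0.169 and 0.133), PSY2 (0.196 and 0.135), HSP18.8 (0.0768 and 0.198), HSP17.9A (0.133 and 0.151), OsPht1;8 (0.149 and 0.268), LOGL1 (0.15 and 0.171), LOGL5 (0.079 and 0.185) and in mhz4 LIP9 (0.316) did not. The LEA list then had camera adjusted p = 0.362 in mhz4 and 0.348 in mhz5, and root markers in mhz4 0.143, while heat shock genes in mhz5 had 0.0279 (adjusted p = 0.628 with an estimated correlation). Root markers then had 1 higher and 1 lower in each mutant, and 0 cell cycle genes passed in mhz4. With mhz4 left out, the mhz5 calls of IAA20 (0.0546), IAA9 (0.0771), PP2C68 (0.0501), IRT2 (0.106), HSP18.8 (0.0561), LOGL5 (0.0604) and OsPht1;8 (0.0592) ended, and the mhz4 calls of LIP9 without mhz1 (0.0594) and NSHB2 without mhz5 (0.0692).

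**Figure D3:**
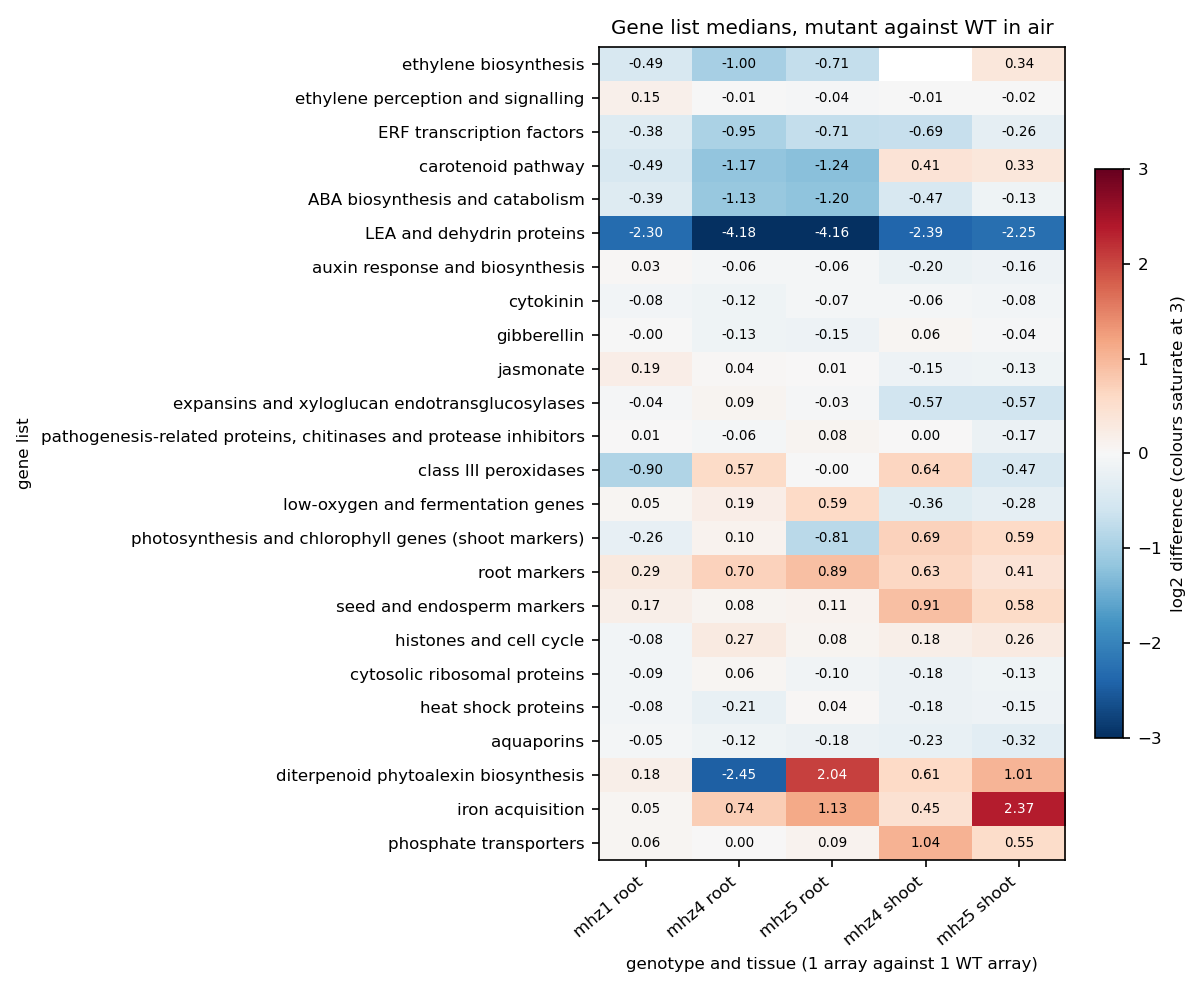
Median log2 difference of each gene list between a mutant array and the WT array of the same tissue in air (lists with at least 2 measured genes, 1 array per group, blank where fewer were measured). LEA and dehydrin genes are lower in all 5 columns (-2.25 to -4.18), and iron acquisition genes have their highest median in mhz5 shoots (2.37).

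Shoots of mhz5 had high transcript levels of iron acquisition genes, which in mhz4 shoots did not pass. In mhz5, NAS2 was higher by 4.21 (SE 0.46, adjusted p = 0.00181), NAS1 by 4.16 (SE 0.58, adjusted p = 0.00435), OsIDS1 by 4.09 (SE 0.28, adjusted p = 0.000212) and NAAT1 by 3.83, and the iron transporter gene IRT1 was higher too (adjusted p = 0.00634). NAS1 read 26611 in air and 36042 in ethylene in mhz5 shoots, against 470 and 5934 in WT and 839 and 2267 in mhz4. In this list 8 of 12 genes were higher in mhz5 (9 adjusted over the list alone), with camera adjusted p = 0.000127 and adjusted p = 0.161 with an estimated correlation, and the median in mhz4 was -0.08. As the list was added after the data were seen, its camera p-values are no independent support. The test of mhz5 against mhz4 itself was not run. Shoots of both mutants had higher BURP16 (5.31 in mhz4 and 4.18 in mhz5), the MADS-box gene MADS56 (3.31 and 2.60), the auxin-response gene SAUR39 (2.54 and 1.55) and, in mhz4, the metallothionein gene MT1B (2.07, SE 0.08, adjusted p = 1.06e-05). Lower in both were the lipid transfer protein gene LTP-2 (-3.69 and -2.97), LEA19 (-3.34 and -3.36), the pectin methylesterase inhibitor gene PMEI8 (-3.17 and -2.86) and Chib3H-a (-2.89 and -2.57), and in mhz5 the phosphatase genes PP2C30 (-2.43) and OsPP2C09 (-2.27).

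Genes of growth-related lists also passed in shoots, while no list did with an estimated correlation. Of 23 expansin and xyloglucan endotransglucosylase genes, 11 were lower in mhz4 and 7 in mhz5 and none was higher, with EXPA7 at -1.29 and -1.26 and EXPB6 at -0.80 and -0.65 (camera adjusted p = 0.014 and 0.000731; adjusted p = 0.514 and 0.261 with an estimated correlation). Of 21 aquaporin genes, 10 were lower and 3 higher in mhz4 (camera adjusted p = 0.0523) and 10 were lower in mhz5 (0.000484; adjusted p = 0.183 with an estimated correlation), including TIP2-1 (-0.98 and -0.87) and PIP2-2 (-1.13 and -0.80). Histone and cell cycle genes were higher, 9 of 32 in mhz4 with 1 lower (camera adjusted p = 0.0549) and 14 of 32 in mhz5 (0.000127; adjusted p = 0.589 with an estimated correlation), among them the replication genes MCM5 (0.57 and 0.89) and PCNA (0.51 and 0.71) and the cyclin gene CYCD5-1 (1.38 and 1.08). Photosynthesis genes were higher in 5 of 13 in mhz4, with RCABP89 at 2.04 and PORB at 1.19 (camera adjusted p = 0.014; adjusted p = 0.743 with an estimated correlation), and in 2 of 13 in mhz5. Ribosomal protein genes were lower in 7 of 21 in mhz4 and 3 in mhz5 (camera adjusted p = 0.014 and 0.0199; adjusted p = 0.564 and 0.589 with an estimated correlation), and heat shock genes in 3 of 18 in mhz5 (camera adjusted p = 0.0146; adjusted p = 0.589 with an estimated correlation). Under quantile normalization the expansin and ribosomal lists in mhz4 had camera adjusted p = 0.0563 and 0.0705, and the ribosomal list in mhz5 had 0.424.

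In the auxin list of 40, 14 genes were lower and 4 higher in mhz4, and 7 lower and 4 higher in mhz5, with IAA31 at -1.18 and -0.90. MHZ4 and ABA8OX2 (-1.27) were lower in mhz4, while the aldehyde oxidase gene AO-2 was higher in both (0.93 and 0.76), as was PSY2 (1.22 and 0.89). The cytokinin-activating enzyme gene LOGL10 was lower (-1.52 and -1.08), the gibberellin synthesis gene OsKAO higher (1.04 and 0.91) and ERS2 lower (-0.77 and -0.73). Both seed storage genes, GLUA-2 (0.88) and GLB (0.59), were higher in mhz4, PRX112 (0.98) was the 1 peroxidase gene of 3 to pass there, and 3 of 5 phosphate transporter genes were higher in mhz4 and 2 in mhz5. In the ethylene biosynthesis list ACS2 was higher in mhz5 (0.71, adjusted p = 0.0444), and ACO1 was lower in mhz4 roots (-1.08, adjusted p = 0.0335); ACS2 was lost with mhz1 left out (0.0694), as was ACO1 (0.0551). No ERF or diterpenoid phytoalexin gene passed in any comparison of a mutant with WT.

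Over both gases 6108 probe sets differed from WT in mhz4 shoots (2924 higher, 3184 lower) and 4165 in mhz5 shoots (2169 higher, 1996 lower). Without the WT shoot air array the counts were 1572 and 747, with only shoot arrays fitted 3536 and 1979, and with mhz4 left out the mhz5 count was 2066. Without that array 6 of the iron genes passed in mhz5 (NAS1, NAS2, OsIDS1, NAAT1, YSL15 and IRO3), IRT1 did not (adjusted p = 0.067), and BURP16, LTP-2, PMEI8, Chib3H-a, EXPA7, EXPB6, TIP2-1, CYCD5-1, PCNA, AO-2, LOGL10 and ERS2 passed in both mutants. LEA19 (0.0942 and 0.114) passed in neither, PP2C30 (0.123), SAUR39 (0.0889), IAA31 (0.0916), PSY2 (0.143), OsKAO (0.0827), PIP2-2 (0.0511) and ACS2 (0.233) were lost in mhz5, and MCM5 (0.0723), ABA8OX2 (0.101), GLUA-2 (0.0933), GLB (0.0503) and PRX112 (0.302) in mhz4. In mhz4, PRX112 was also lost with mhz1 or mhz5 left out (0.0577 at most) and MCM5 with mhz1 left out (0.0535), and SAUR39 in mhz5 with mhz4 left out (0.0507). Without the array the photosynthesis list in mhz4 had camera adjusted p = 0.0822, the ribosomal list in mhz5 0.053, and the cell cycle and aquaporin lists in mhz4 0.0014 and 0.0209 (adjusted p = 0.657 each with an estimated correlation). In mhz4, 1 iron gene was then lower. In that fit 4 expansin genes were lower in mhz4 and 2 in mhz5, 2 aquaporin genes were lower and 1 higher in mhz4 and 2 lower in mhz5, and 3 cell cycle genes were higher in mhz4 and 9 in mhz5. Only 2 photosynthesis genes were then higher in mhz4 and 0 in mhz5, 4 auxin genes were lower and 1 higher in mhz4 and 0 passed in mhz5, 1 heat shock gene was lower in mhz5, and 0 ribosomal protein or phosphate transporter genes passed in either mutant.

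The changes of mhz4 and mhz5 overlapped. In roots 718 probe sets were higher and 987 lower in both, against 67.4 and 98.8 for independent lists, and in shoots 1491 and 1428, against 274 each. Both mutants were set against the same WT arrays, which alone gives a correlation: unchanged groups simulated against a shared WT array correlated at 0.501, against 0.777 observed for mhz4 and mhz5 in root air and 0.861 in shoot air. The covariances were 0.235 and 0.282, and the simulated shared array gave 0.0369. The simulation gave that array the noise of any other, so a WT array standing apart could give more. With no array shared, which sets 1 mutant in air beside the other in ethylene, mhz4 and mhz5 correlated at 0.556 and 0.54 in roots and at 0.497 and 0.647 in shoots. Their covariances were then 0.127 and 0.121 in roots and 0.123 and 0.1615 in shoots, lower than with the shared array. For mhz1 the correlations in root air were 0.577 with mhz4 and 0.546 with mhz5, and 0.212 to 0.354 with no array shared. Its calls over both gases also overlapped with those of mhz4 and mhz5 roots. With mhz4, 137 of 191 higher and 70 of 98 lower probe sets were shared, against 12.8 and 8 for independent lists. With mhz5, 93 and 55 were shared, against 8.3 and 5.12. Both WT root arrays carry the mark mb, so a difference of WT roots tied to it would remain with no array shared. Part of the overlap of calls may come from the shared WT arrays, since WT had 1 array per gas.

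Roots and shoots differed most. Of 20374 probe sets compared, 4162 were at least 2-fold apart in the same direction in all 6 pairs of arrays (3 genotypes and 2 gases), 1769 higher in root and 2393 higher in shoot. All 13 measured photosynthesis genes were higher in shoot in every pair (median -6.80 root minus shoot), and 6 of 13 root markers were higher in root with none higher in shoot (median 2.27). Histone and cell cycle genes were higher in root in 14 of 30. Only 2 seed and endosperm genes were measured in both tissues, and neither was 2-fold apart in all pairs.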

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

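The tests of a difference between root and shoot, the tests on the dehydrin genes with mhz1, the test on iron acquisition genes, the shoot distance test and the counts of other splits were chosen only after the result was seen. The test on PP2C genes over both gases and the distance test with mhz1 as a second reference were written before their results.

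Ethylene effects differed between root and shoot at 129 probe sets in limma's test of the difference. ADC2 fell in roots (-3.27) and had -0.45 in shoots (adjusted p of the difference = 0.00837), the gene SAT1 had 0.35 and -0.57 (0.0272), and the zinc transporter gene ZIP4 had 0.43 and -0.88 (0.00637). Only 5 probe sets passed in both tissues with opposite signs. The count was 195 without the WT shoot air array and 67 without the WT root air array.

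The mhz4 effect differed between tissues at 5583 probe sets. In both tissues 575 probe sets passed with opposite signs, while 276 were higher in both and 328 lower in both. Independent lists would share 196 higher and 260 lower, and their number with opposite signs was not worked out. NSHB2 had 2.84 in root and -2.49 in shoot, SAUR39 -1.18 and 2.54, the germin-like gene GER3 -2.28 and 0.94, and the sucrose synthase gene SUS4 -1.36 and 1.67. Without the WT air array of the tissue none of these 4 passed in both: NSHB2 (adjusted p = 0.131 in root and 0.369 in shoot) and SUS4 (0.302 and 0.116) passed in neither, SAUR39 was lost in root (0.17) and GER3 in shoot (0.0629). BURP16 had 0.54 in root and 5.31 in shoot. Without the WT shoot or root air array the count was 2479 or 2741.

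The mhz5 effect differed at 2518 probe sets. In both tissues 169 probe sets passed with opposite signs, while 258 were higher in both and 212 lower in both (94.3 and 104 for independent lists). The iron genes OsIDS1 (0.55 in root, 4.09 in shoot), NAS2 (0.84 and 4.21) and NAS1 (0.76 and 4.16) were among the 2518, with the same sign in both tissues and adjusted p of the difference of 0.00589, 0.0205 and 0.0358. The count was 645 without the WT shoot air array and 665 without the WT root air array.

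High iron acquisition transcripts in mhz5 shoots were weighed against root tissue carried into the mhz5 shoot samples. Root tissue would have to make up 63.6% of the mhz5 shoot sample in air, in the median over NAS1, NAS2 and NAAT1, to give their signals. Over 97 other probe sets with root-specific signal the median share was 0.02% in air and -0.363% in ethylene, which argues against carried-over root. An effect of the mutation on iron acquisition in shoots may remain as a hypothesis, and how the seedlings were supplied with iron is not in the labels and was not tested.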

How the results depend on the processing

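The omission of a WT air array, the ethylene arrays in place of the air arrays, and the alternatives of the contrasts between tissues were chosen only after the results were seen. With 1 array per group, no setting separates a genotype from the growth of its seedlings, and dim probe sets near the signal filter carry the least information.

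No paired analysis was possible by replicate number because each group had 1 array, and the limma fit already sets the air and ethylene arrays of a genotype and tissue side by side.

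No result past its threshold changed direction. Without the WT root air array, the median of the LEA list in mhz1 roots, not past it, went from -1.10 to 0.71, and without the WT shoot air array that of the ERF list in mhz4 shoots from -0.06 to 0.57. Camera at the preset correlation was recomputed under quantile normalization and without a WT air array. The result was the same in 387 tests, which includes tests past the threshold in neither setting, while 7 calls were gained and 14 lost. The estimated correlation is not part of these counts. Of the list medians 294 stayed within 0.1 under quantile normalization and 4 moved. Recomputed results of genes in limma comparisons were the same in 3570 cases and calls were lost in 832, and those of genes in comparisons of single arrays stayed in 190 and moved in 134.

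With ethylene arrays in place of air arrays, probe sets 2-fold from WT numbered 775 and 774 in mhz4 and mhz5 roots and 974 and 609 in their shoots. Responses on probe sets chosen at 1.5-fold were 0.81 (WT), 0.86 (mhz1), 0.52 (mhz4) and 0.51 (mhz5) in roots and 0.32 (WT), 0.52 (mhz4) and 0.56 (mhz5) in shoots, as a lower threshold takes in smaller changes. The WT shoot response was 0.81 with a pseudocount of 64, and the cause was not tested.

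Without the WT air array of the tissue, limma called 650 probe sets for ethylene in roots and 781 in shoots, 66 for mhz1 roots, 853 and 644 for mhz4 and mhz5 roots, and 1572 and 747 for their shoots. The tissue contrasts gave 195 (ethylene), 2479 (mhz4) and 645 (mhz5) without the WT shoot air array, and 67, 2741 and 665 without the WT root air array. Most counts fell, although the shoot ethylene count and, without the WT shoot air array, the ethylene contrast between tissues increased. For mhz4 the number of arrays fitted does not by itself account for the fall. With mhz5 left out, which removes more arrays, 6013 probe sets were called in mhz4 shoots and 3170 in mhz4 roots. With mhz1 left out the counts were 5112 and 2701. In mhz1 roots 67 were called with mhz4 left out, so the number of arrays stays open there. Without its air array, WT in that tissue rests on the ethylene array alone, and the cause was not tested. With only the arrays of the tissue, counts were 210 for ethylene in shoots, 118 for mhz1 roots, and 3536 and 1979 for mhz4 and mhz5 shoots. In those fits 155 recomputed gene results lost their call and 274 stayed the same, and the genes concerned are not named here.

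Leaving out a genotype gave 499 to 1043 calls for ethylene in roots and 139 to 786 in shoots. It gave 67 to 189 for mhz1 roots, 1253 to 1754 for mhz5 roots and 2066 to 3230 for mhz5 shoots.

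Correlations between mutants with no array shared were 0.354 and 0.316 (mhz1 and mhz4), 0.212 and 0.252 (mhz1 and mhz5), 0.556 and 0.540 (mhz4 and mhz5 roots) and 0.497 and 0.647 (shoots), where 1 mutant in air was also set beside the other in ethylene, so the cause was not tested.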

Other observations

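The tests on the dehydrin genes with mhz1, the PP2C values split by gas or set against mhz1, the tests on the shoot distances and on other splits were chosen only after the result was seen.

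Diterpenoid phytoalexin genes, which make antimicrobial compounds of rice, stood apart in opposite directions in the roots of mhz4 and mhz5. In air their median difference from WT was -2.45 in mhz4 (6 measured, percentile 0.0) and 2.04 in mhz5 (8 measured, percentile 100). The ethylene responses (1.63 in mhz4, -2.69 in mhz5, -0.19 in WT and -0.22 in mhz1) use the same mutant air arrays, so that they add no support of their own. The random lists behind the percentiles ignore the correlation between members, estimated at 0.740. No member passed in limma, whose fit takes both gases together, and each value rests on 1 pair of arrays. The list was added after the data were seen.

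Dehydrin and LEA genes were lower with ethylene in WT roots and low already in mhz4 and mhz5 roots. A WT air array standing apart alone is argued against by mhz1 roots, where the median ethylene response was -2.59, and by the root air arrays of mhz4 and mhz5, whose medians lay -2.28 and -2.16 from mhz1. All of these values use the same mhz1 root air array, so they are not independent of each other. Lower ABA action in both mutants would lower other ABA-signalling PP2C genes, and over OsPP2C08, PP2C51 and PP2C53 the median root difference was -0.47 (-0.80 to 0.02). That met the bound of -0.3 written beforehand, with -0.56 in air, but without the WT root air array the medians were -0.18 (ethylene) and -0.28 (air, from mhz1), and in limma PP2C51 was too dim and only PP2C53 in mhz4 passed (adjusted p = 0.0215; the others tested had 0.0564 to 0.0929). In root ethylene the LEA list had median signals of 89.2 in WT, 102.6 in mhz4 and 90.8 in mhz5. With no LEA difference to explain there, the ethylene value cannot decide. In root air the list read 821 in mhz1 and 4079 in WT, so lower ABA action could leave a smaller difference from mhz1 than from WT. Lower ABA action may therefore be a cause and stays open, since the bound was met only with the WT root air array, and water status was not tested. The rule of this test left out the PP2C genes already named, PP2C30 and PP2C68, which were lower in roots of both mutants.

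Arrays of mhz4 and mhz5 lay closer to WT in ethylene than in air. In roots 1460 and 1317 probe sets were 2-fold from WT in air, against 775 and 774 in ethylene. With mhz1 as the reference the air-over-ethylene ratios were 1.31 for mhz5 and 1.85 for mhz4. The rule written beforehand took at least 1.3 in both to speak against a WT root air array standing apart, and these ratios met it. Over settings computed after the ratios were seen, mhz4 ran from 1.80 to 1.92 and mhz5 from 1.26 to 1.34. In mhz5 a WT root air array standing apart can therefore not be told apart from a loss of air-specific differences. In shoots the ratios against WT were 1.89 and 2.26, and no genotype near WT was measured there as a second reference. A smaller difference in ethylene may be biological, since dehydrins were low in WT roots in ethylene and in mutant roots in air, and that stays a hypothesis.

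Of 35 splits of the 8 root arrays 32 could be fitted, and since a genotype with both arrays on 1 side adds nothing, 20 of them differ in the fit. These are too few for a share under 0.05: 1 gave as many ethylene calls, the real one with 1139, and the highest other had 249. Among the 8 that part every genotype the highest other had 1. The shoot arrays have 7 splits that differ in the fit (of 10), also too few: 1 gave as many, the real one with 512, and the highest other had 12.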
